A study of Rattus norvegicus with 9 samples.

How the data were processed

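The data were 10x Genomics 3' single-cell RNA-seq libraries (version 3 chemistry) of rat sciatic nerve, 3 per group: sham, 3 days after crush and 7 days after crush. For each sample the deposited files held a matrix of UMI counts per gene and cell barcode with its gene and barcode lists. The counts were made by the authors with Cell Ranger 7.0.1, per the file headers, and the submitters' processing notes name Cell Ranger, STAR and the genome build Rnor_6.0. The barcode lists had already been reduced to called cells, and the deposited counts were whole numbers with no normalization. The annotation release behind the 32623 genes is not given in the sources used here, and no genome sequence was used. Groups and replicate numbers came from the labels. The labels do not say whether replicates were separate animals, so p-values measure only the spread between these samples, which may be technical.

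The samples held 136849 barcodes. Cells with at least 300 genes and at most 20% of UMIs from mitochondrial genes were kept (133501 cells). Doublets were scored per sample with Scrublet in scanpy 1.11.5, and the top-scoring 0.8% per 1000 cells kept by these filters were dropped, 9.674% to 14.12% of a sample or 16101 cells in all. Cells were scaled to 10000 UMIs, logged and clustered together on 2000 variable genes, 30 principal components and 20 nearest neighbours, with no batch integration, by the Leiden method (leidenalg 0.10.2, resolution 1) on python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and igraph 0.11.9. Of 49 clusters, 28 were named, 5 were left unnamed and 16 were left out as doublets (1198 further cells), which left 116202 cells. A doublet cluster had over 50% of its cells scored, or over 40% and more than 1.5 times the median UMIs of the sample.

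Cluster names came from cell type markers fixed before the data were examined, as were the tests, the gene lists, the rule for named genes and the alternatives, apart from the choices said to have been made after the data were seen. A marker counted for a cluster when found in at least 10% of its cells at 2 or more times the CPM of the median cluster, and the class with most markers among the top 10 genes by fold, then with most markers counted, gave the name. Clusters with fewer than 3 markers stayed unnamed, as did those led by MHC class II genes (4 or more of the top 10) and those with few UMIs and no marker of their class among the top 10. These thresholds were set after the clusters had been seen. Pecam1, Col1a2, Ccr2, Cd79a, Ackr1 and some other listed symbols were not analysed here, because they matched no gene under that symbol.

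Shares of cells were computed per sample and compared with an exact permutation test over the 3 groups (280 partitions) and a two-sided exact permutation test for each pair. For endothelial-like, Schwann-like, fibroblast-like and macrophage or monocyte-like cells, and for all kept cells, raw counts were summed per sample over cells. In that order the sums held 3885492 to 7206679, 1565946 to 22840504, 46448473 to 82462827, 2531577 to 22559532 and 92601504 to 115644535 UMIs per sample. They were tested with edgeR 4.0.16 (R 4.3.3, TMM normalization, filterByExpr, robust quasi-likelihood F test) in 1 fit of all 9 samples per class, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called higher or lower. Adjusted p-values given for genes come from this fit unless DESeq2 is named, which was run on the same filtered genes without its independent filtering. That filtering was turned off after the data were seen, because its threshold differed between runs and moved adjusted p-values. CPM values are means ± SD of 3 samples and log2 fold changes are given ± SE. Genes tested numbered 11837, 14438, 15986, 12937 and 17449. The common biological coefficient of variation was between 0.0394 and 0.0505, so that small differences passed the threshold.

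Of 19 fixed gene lists, each class was tested for those fitting it with fry in limma 3.58.1, with Benjamini-Hochberg adjustment over 93 tests. Its one-way p asks whether a list's genes move on balance in 1 direction and its either-way p whether they change in any direction, and neither compares the list with other genes. Genes named in the text were the 5 largest rises and 5 largest falls against sham and the 3 largest each way between day 7 and day 3, among called genes with a mean of at least 50 CPM in the higher group, no overlap between samples of the groups, and at least 50% of the CPM of the class where the gene was highest. Added to these were up to 3 called members per list, and Ntn1 and the netrin receptors. Vwf, Gapdh, Tpi1, Spp1, Cd163 and a few further genes are given in comparisons other than the one that named them. Ntn1 shares were also computed after thinning each cell to 1500 UMIs, with exact 95% binomial intervals.

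The tests were tried on simulated counts for day 3 versus sham with 200 changed genes. These were drawn from genes above a minimum mean count and were far fewer than the real comparisons called. The shares below therefore do not hold for genes with few counts, nor for a setting where most genes change. Of genes changed 1.5-fold, 84% were recovered in endothelial-like, 58% in Schwann-like, 90% in fibroblast-like and 60% in macrophage or monocyte-like cells, and of genes changed 2-fold 100%, 88%, 98% and 90%. Unchanged genes made up 4.5%, 7.14%, 6.28% and 6.95% of calls. The alternatives were DESeq2 size factors, DESeq2 1.42.0, no filter on low counts, the replicate number as a block, only the 6 samples compared, doublets kept, a stricter cell filter (1000 genes and 10% mitochondrial), libraries thinned to the smallest, each library left out, and for shares a Leiden resolution of 2, classes by marker share per cell, clustering without called genes and an edgeR test of cell counts. A count of own-class genes, those whose CPM in the higher group was 50% or more of that of the class where it was highest, was added after the data were seen. Some single genes that met the naming rule are not reported here. Figures were drawn with matplotlib 3.10.9.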

Results

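Single-cell gene expression was measured in rat sciatic nerve, the large mixed nerve of the hind limb, without injury (sham) and at 3 and 7 days after a crush injury, which cuts axons off from their cell bodies while leaving the nerve sheath in continuity. Each of the 3 groups held 3 samples, 9 in all. The count tables listed 12501 to 18219 cell barcodes per sample, with a total of 113817398 to 143744517 UMIs (unique molecular identifiers, 1 per captured transcript) and a median of 6364 to 7724 UMIs per barcode. After filtering and removal of doublets, 116202 cells remained for the comparisons. The series title names netrin-1, a secreted guidance protein encoded by Ntn1, and endothelial exosomes, and the comparisons below asked how the cell makeup, the state of 4 cell classes and Ntn1 itself changed after crush.

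Crush changed the cell makeup of the nerve at both times. Fibroblast-like cells made up 60.5% ± 0.653 of kept cells in sham (mean ± SD of samples, n = 3), 27.0% ± 0.642 at day 3 and 37.4% ± 1.15 at day 7. Schwann-like cells, the glia that ensheathe axons, made up 4.53% ± 0.316 in sham, 18.7% ± 0.110 at day 3 and 23.6% ± 0.345 at day 7. Macrophage or monocyte-like cells rose from 7.20% ± 0.228 to 24.9% ± 0.262 at day 3 and stood at 13.4% ± 0.348 at day 7. Neutrophil-like cells, the first granulocytes to enter injured tissue, were at 0.104% in sham (26, 9 and 9 cells in the 3 samples), 7.22% at day 3 and 0.401% at day 7. Without sham replicate 1 the sham mean would be over 1.5 times lower.

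Endothelial-like cells fell from 8.86% ± 0.325 of cells in sham to 5.77% ± 0.425 at day 3 and 4.54% ± 0.202 at day 7, and mural-like cells (pericytes or smooth muscle) were at 6.61%, 3.31% and 4.58%. Lymphatic endothelial-like cells were at 2.06% ± 0.151, 0.563% ± 0.112 and 0.173% ± 0.188 in sham, day 3 and day 7; replicate 2 held 49 of the 67 day 7 cells. T or NK-like cells stood at 1.34%, 2.04% and 3.06%, and B or plasma-like cells at 0.309%, 1.498% and 0.917%. Mast-like cells made up 0.563%, 0.112% (14, 23 and 0 cells in the 3 samples) and 0.0450% (0, 17 and 0 cells), and perineurial-like cells, from the sheath around each nerve fascicle, 0.333%, 0.0563% (8, 3 and 8 cells) and 0.0168% (4, 0 and 3 cells). The day 7 means of these 3 classes and the day 3 mean of mast-like cells would move by 1.5 times or more without 1 library. Over the 3 groups, the exact permutation test gave p = 0.003571 for 9 of the 11 classes, the smallest of 280 partitions, with a Benjamini-Hochberg adjusted value of 0.004365. For perineurial-like cells the exact p was 0.007143 (adjusted 0.007857) and for mast-like cells 0.04286, before and after adjustment, a call lost without any 1 of 7 libraries (adjusted p = 0.0821 to 0.179). In pairs of groups the exact test could not go below 0.1, and it gave 0.1 for every difference except those between day 7 and day 3 of mast-like cells (0.7) and perineurial-like cells (0.2). Shares are of recovered cells, so a rise of 1 class lowers the others. Cells in clusters left without a name made up 7.54% ± 0.200, 8.79% ± 0.527 and 11.8% ± 0.839 in sham, day 3 and day 7. Among these, cluster 12, led by MHC class II genes, made up 4.78%, 2.92% and 3.28%, and cluster 19 0.0930%, 2.67% and 4.26%. Such cells count in no class, and whether any belong with macrophage or monocyte-like cells was not settled. The direction of several small classes turned under other ways of drawing classes, with values given under the alternatives: mural-like and B or plasma-like cells at day 7, lymphatic endothelial-like cells at both days, neutrophil-like cells at day 7 versus sham, perineurial-like cells at day 3, and mast-like and perineurial-like cells at day 7 versus day 3. The mast-like one also turned with doublets kept.

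**Figure D1:**
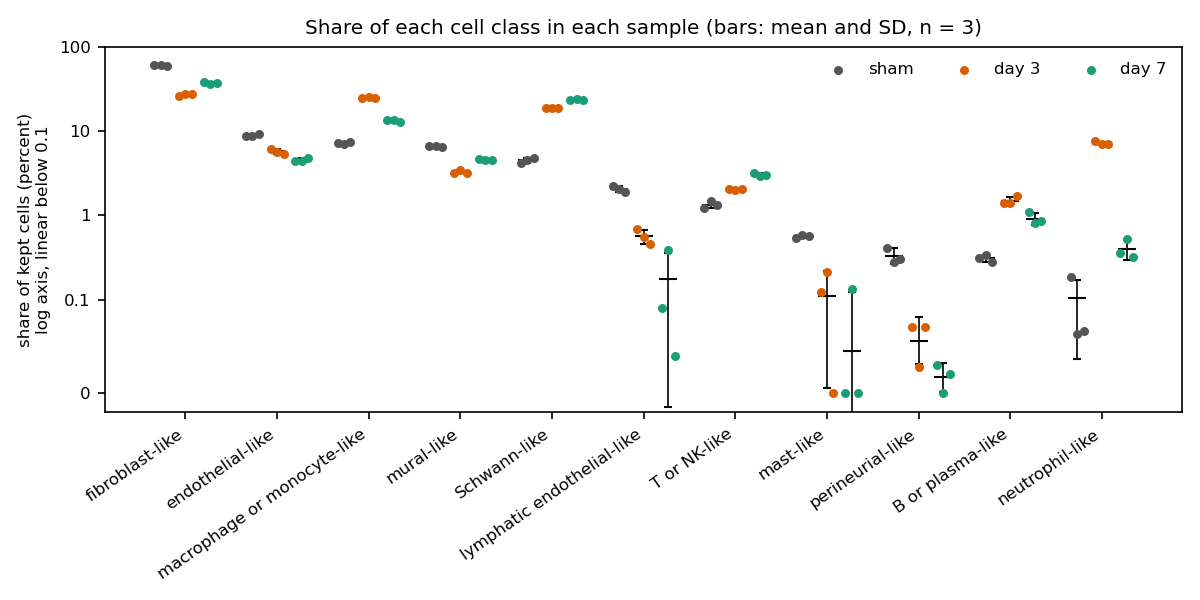
Share of kept cells (percent, log axis that is linear below 0.1) for each of 11 cell classes in sham, day 3 and day 7; points are samples and bars the mean and SD of 3 samples. Fibroblast-like cells fell from a mean of 60.5% to 27.0% at day 3, and neutrophil-like cells reached 7.22% at day 3 against 0.104% in sham.

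At day 3, endothelial-like cells, which line the blood vessels, held fewer transcripts of leukocyte adhesion receptors and of the receptors for vascular endothelial growth factor (VEGF) than in sham, and more mitotic transcripts. Selp, which encodes the adhesion receptor P-selectin, fell from 1354 ± 39.4 CPM (counts scaled to the library size; mean ± SD, n = 3) to 309 ± 29.4 CPM, a log2 fold change of -2.13 ± 0.06 (SE; adjusted p = 1.05e-32). Sele, encoding E-selectin, fell 4.05-fold to 103 ± 5.10 CPM, and Flt1 and Kdr, which encode VEGF receptors, fell 2.33-fold and 2.39-fold. Ube2c, whose product helps degrade cyclin B at the end of mitosis, rose from 4.66 ± 1.90 to 77.4 ± 12.3 CPM (log2 fold change 4.04 ± 0.38, adjusted p = 8.78e-05). In this comparison 3842 of 11837 tested genes were higher and 3741 lower at day 3. Selp and Sele, and Cytl1 named below, were among the top 10 genes of cluster 25. This cluster held 48.6% of endothelial-like cells in sham, but 1.14% at day 3 and 2.16% at day 7. Whether the falls of these genes came from this changed mix of clusters or from changes within cells was not tested.

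The 5 largest falls at day 3 by the fixed rule were Cytl1 (508 ± 4.04 to 57.1 ± 5.70 CPM, log2 fold change -3.16 ± 0.06), Mid1 (-2.92), Igf2 (insulin-like growth factor 2, -2.48), C1qtnf9 (-2.47) and Nr5a2, a nuclear receptor (-2.36). The 5 largest rises were genes of division or nucleotide metabolism: Ube2c, the kinetochore gene Spc24 (3.87 ± 0.13), the securin gene Pttg1 (3.39), Cdkn3 (3.16) and Dctpp1, encoding dCTP pyrophosphatase (2.92). At day 3 all 5 had a higher CPM in Schwann-like than in endothelial-like cells. Of the cell cycle list, 22 of 24 tested members rose and 2 fell (median log2 fold change 2.37; fry one-way adjusted p = 6.12e-06), Ccnb1, encoding cyclin B1, rising 17.4-fold.

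Leukocyte adhesion and cytokine genes fell together: 12 of 15 members fell and 1 rose (median -0.55, fry adjusted p = 3.77e-07), with the cytokine gene Il6 falling from 262 ± 3.88 to 78.6 ± 6.08 CPM. Of the junction and barrier list, 10 of 15 members fell and 2 rose (median -0.52, fry adjusted p = 2.04e-06). Jam2, a junctional adhesion molecule gene, fell 1.89-fold and the drug exporter gene Abcg2 1.85-fold, while the exporter gene Abcb1a, at a higher CPM in Schwann-like cells, rose 1.76-fold. Adjusted over the list alone, 11 junction members fell. The sprouting and tip cell list went both ways, with 7 of 21 members higher, 8 lower and a median of -0.04 (fry one-way adjusted p = 0.00171, either way 1.45e-08).

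The hypoxia and glycolysis list split at day 3: 9 of 20 members rose, among them Pgk1 (1.41 ± 0.06), Gapdh (1.57) and Tpi1 (1.56), and 9 fell (median 0.14, fry adjusted p = 0.00304). Of guidance genes other than netrin, 5 of 21 rose and 10 fell (median -0.40, fry adjusted p = 3.86e-04). Adjusted over the list alone, 6 guidance members rose. In the list for extracellular vesicle release, the route by which exosomes leave cells, 7 of 14 members fell and 3 rose (median -0.17, fry adjusted p = 8.59e-05). Rab27a, a small GTPase gene of vesicle docking, fell from 59.9 ± 3.99 to 14.9 ± 1.20 CPM, and Smpd3, encoding neutral sphingomyelinase 2, from 13.8 ± 1.42 to 1.49 ± 0.568 CPM, although Smpd3 was higher in sham fibroblast-like cells (129 ± 3.35 CPM). Immediate early genes, which also respond to tissue dissociation, fell in 13 of 14 cases (median -0.62). The same number fell at day 3 in Schwann-like, fibroblast-like and macrophage or monocyte-like cells. A difference in dissociation between the groups was not tested and cannot be told apart from crush here. The other lists gave the same counts adjusted over the list alone. The sham cells lay mainly in clusters 25 (48.6%) and 18 (48.3%) and the day 3 cells in cluster 17 (79.4%), with median depths of 4617 and 7176 UMIs. Transcripts of other classes moved with the groups: the summed CPM of 17 fibroblast markers in endothelial-like cells was 9481 in sham, 2033 at day 3 and 3619 at day 7, and that of 16 macrophage or monocyte markers 345, 714 and 690. The median mitochondrial share of UMIs was 2.87%, 3.54% and 4.25%. Of the 5096 own-class genes (those at 50% or more of the CPM of the class where they were highest), 1889 were higher and 1787 lower.

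At day 7, the endothelial changes against sham included a fall of adhesion genes and rises of Igfbp2 and Nox4. Selp stood at 263 ± 5.97 CPM (log2 fold change versus sham -2.36 ± 0.06, adjusted p = 3.96e-34), and Vwf, encoding von Willebrand factor, at 107 ± 4.02 CPM against 255 ± 3.41 in sham (-1.25 ± 0.06, adjusted p = 2.43e-23). Igfbp2, which encodes a binding protein of insulin-like growth factors, rose from 1.07 ± 0.193 to 53.8 ± 1.13 CPM (5.63 ± 0.27, adjusted p = 1.89e-11), and Nox4, encoding an NADPH oxidase, from 9.35 ± 1.44 to 53.9 ± 2.27 CPM. Higher genes numbered 3890 and lower genes 3804 of 11837.

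The other large rises at day 7 were Npw, encoding neuropeptide W (2.79), Ddah1 (2.45) and the matrix gene Vwa1 (2.37), and the largest falls were Cytl1 (-3.89), Ltbp1, encoding a protein that binds latent TGF-beta (-2.80; higher in fibroblast-like cells), Igf2 (-2.75), Apol9a (-2.69) and Mid1 (-2.59). Of the adhesion and cytokine list 12 of 15 fell (median -0.51, fry adjusted p = 4.31e-07) and of the junction list 11 of 15 (median -0.64, fry adjusted p = 4.59e-07). Cell cycle members rose in 21 of 24 cases (median 1.82, fry adjusted p = 9.97e-05). Sprouting genes rose in 9 and fell in 8 of 21 cases (median 0.14), and the fry adjusted p of 0.0221 became 0.102 without sham replicate 1 and 0.0538 without sham replicate 3. Guidance genes split into 7 higher and 9 lower, and 10 lower adjusted over the list alone, Sema3d, highest in lymphatic endothelial-like cells, falling 10.1-fold and Sema3e rising 7.54-fold. The fry adjusted p of the guidance list, 0.0428, rose to between 0.0549 and 0.151 without day 3 replicate 1 or any 1 of the day 7 libraries, and to 0.0791 with the replicate number as a block. Of vesicle release members, 5 of 14 fell (fry adjusted p = 1.72e-04). In the hypoxia list 9 rose and 8 fell; its median (0.16) was above 0 while fry pointed down (adjusted p = 0.221). Immediate early genes split into 7 higher and 7 lower, with a median of 0.01, a mean of -0.09 and a downward fry direction (adjusted p = 0.200). The remaining lists had equal counts adjusted over the list alone. Day 7 cells lay mainly in cluster 17 (70.7%), with a median of 5130 UMIs. Of 5287 own-class genes, 1983 were higher and 1849 lower.

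Between day 3 and day 7, mitotic transcripts fell in endothelial-like cells and the capillary gene Gpihbp1 rose. Gpihbp1, which anchors lipoprotein lipase on capillaries, rose from 85.9 ± 21.8 to 343 ± 11.2 CPM (log2 fold change 1.98 ± 0.17, adjusted p = 1.92e-04), C1qtnf9 from 11.2 ± 3.38 to 62.7 ± 16.4 CPM and the imprinted gene Mest from 20.02 ± 2.11 to 80.0 ± 9.06 CPM. The largest falls were in Trib3 (-2.04 ± 0.11) and Sesn2 (-1.37 ± 0.07), genes induced by amino acid and other cell stress, and in Vwf (-1.14 ± 0.06). Genes higher at day 7 numbered 1612 and lower genes 1717. Of the cell cycle list 19 of 24 fell (median -0.52, fry adjusted p = 0.00106) and of the hypoxia list 10 of 20, or 11 adjusted over the list alone (median -0.32). Sprouting members rose in 10 of 21 cases, 11 adjusted over the list alone (median 0.23, fry adjusted p = 2.21e-04), with Kdr 1.41-fold higher. Guidance members rose in 8 cases (9 adjusted over the list alone; fry adjusted p = 0.00497) and immediate early members in 11 (12 adjusted over the list alone; fry adjusted p = 1.75e-05). Junction genes fell in 7 of 15 cases (fry adjusted p = 8.59e-05). The adhesion list had 4 higher and 5 lower (fry adjusted p = 0.0559), and the vesicle list 2 and 2, with a median of 0.02 and an upward fry direction (adjusted p = 0.253) but a mean of -0.04; list-alone counts were equal for the junction, adhesion, vesicle and cell cycle lists. DESeq2 called 1098 genes lower, and of 5345 own-class genes 767 were higher and 810 lower.

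Schwann-like cells at day 3 held less of the transcripts of myelin, the lipid sheath around axons, than in sham and more of those of division. Mag, encoding myelin-associated glycoprotein, fell from 67.8 ± 18.7 CPM (n = 3) to 2.46 ± 0.330 CPM (log2 fold change -4.78 ± 0.19, adjusted p = 2.07e-14). Egr2, the transcription factor gene that drives myelination, fell 10.5-fold to 25.5 ± 2.64 CPM, and Mal, a myelin proteolipid gene, 9.86-fold. Hmga2, a chromatin protein gene of proliferating cells, rose from 9.58 ± 4.37 to 253 ± 4.84 CPM (4.72 ± 0.12, adjusted p = 3.35e-25), and Ucn2, encoding urocortin 2, 12.7-fold. In all, 4351 of 14438 tested genes were higher and 3872 lower at day 3.

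The largest falls at day 3 also took in the transporter gene Abca8a (1076 ± 6.41 to 43.8 ± 1.52 CPM, -4.62 ± 0.05), the matrix protein gene Sparcl1 (-4.55), Adamts17 (-4.38) and the immediate early gene Egr1 (-4.21), and the largest rises Sapcd2 (3.99), Ccnb1 (3.98) and Pmepa1, a TGF-beta target (3.62). Of the myelin list 14 of 17 tested members fell and 2 rose (median -1.88, fry adjusted p = 1.19e-07). Cholesterol synthesis genes, which supply myelin lipid, fell in 14 of 18 cases and rose in 0 (median -1.19, fry adjusted p = 2.49e-08), with Hmgcs1 falling 4.196-fold. All 24 tested members of the cell cycle list rose (median 2.22, fry adjusted p = 3.05e-06). The repair Schwann cell list split, 10 of 19 members rising, Shh (sonic hedgehog) 6.91-fold to 5.06 ± 0.455 CPM, and 7 falling, among them Bdnf (-2.76). Its median was 0.66, its fry one-way adjusted p 0.833 and its either-way adjusted p 1.32e-10. Growth factor genes rose in 8 and fell in 9 of 21 cases (median -0.34, fry adjusted p = 3.73e-05), Fgf2 falling from 135 ± 8.67 to 27.7 ± 1.69 CPM. Immediate early genes fell in 13 of 14 cases (median -2.29). Counts adjusted over the list alone were equal for these 6 lists. Of sham cells 88.8% lay in cluster 23 and of day 3 cells 64.1% in cluster 13, and the median depth was 2266 UMIs in sham against 8390 at day 3. The fibroblast marker sum in Schwann-like cells was 15258 CPM in sham, 3474 at day 3 and 5018 at day 7, the macrophage marker sum 414, 671 and 674 CPM and the median mitochondrial share 4.33%, 3.41% and 4.94%. Of 8374 own-class genes, 3349 were higher and 2044 lower.

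By day 7 a part of the myelin program stood closer to sham in Schwann-like cells, and a neurofilament gene had come up. Mag was at 15.8 ± 1.90 CPM (log2 fold change versus sham -2.11 ± 0.15, adjusted p = 2.03e-10). Nefl, which encodes the neurofilament light chain known from axons, rose from 1.68 ± 1.22 in sham to 75.0 ± 4.29 CPM (5.52 ± 0.22, adjusted p = 1.54e-20). Ccn2, a matricellular growth factor gene, rose 13.9-fold to 140.2 ± 6.496 CPM. Higher genes numbered 4361 and lower genes 3684.

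Hmga2 (4.13), Ccnb1 (3.95) and Sapcd2 (3.78) completed the 5 largest rises, and the largest falls were Csmd1 (-6.31), Sparcl1 (-5.33), Abca8a (-4.68), Fxyd7, a sodium pump regulator gene (-4.05) and the collagen gene Col28a1 (-3.96). In the myelin list 8 of 17 members fell and 5 rose against sham, 6 adjusted over the list alone (median -0.62, fry adjusted p = 2.08e-06). Cholesterol synthesis genes fell in 15 of 18 cases (median -1.36, fry adjusted p = 2.19e-08), Lss 3.55-fold. Cell cycle genes rose in 23 of 24 cases (median 1.96, fry adjusted p = 8.37e-06). Of the repair list 10 members rose, 11 adjusted over the list alone, and 6 fell; its median (0.46) and mean were above 0 while fry pointed down (adjusted p = 0.211). Growth factors split into 7 higher and 8 lower (fry adjusted p = 6.21e-05), and immediate early genes fell in 12 of 14 cases (median -1.09). Day 7 cells lay in clusters 9 (49.6%) and 16 (33.0%), at a median of 5901 UMIs, and of 8388 own-class genes 3419 were higher and 1867 lower.

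From day 3 to day 7 the myelin genes of Schwann-like cells rose as a group. Cldn19, a claudin gene of myelin tight junctions, rose from 7.87 ± 1.27 to 85.5 ± 3.31 CPM (log2 fold change 3.45 ± 0.10, adjusted p = 3.27e-15), and Pmp2, encoding a peripheral myelin fatty acid-binding protein, from 35.7 ± 1.69 to 273 ± 7.07 CPM (2.93 ± 0.17). The heat shock gene Hspa1b was also among the 3 largest rises (2.95), and the largest falls were in Sesn2 (-2.00 ± 0.05), Nkd2, a Wnt antagonist gene (-1.80), and Mapt, encoding the microtubule protein tau (-1.78). Of the myelin list 14 of 17 members rose and 0 fell (median 0.99, fry adjusted p = 8.03e-08), Mag 6.36-fold and Egr2 2.34-fold. Cell cycle genes fell in 18 of 24 cases (median -0.31, fry adjusted p = 4.06e-04) and cholesterol synthesis genes in 9 of 18, with 3 higher (fry adjusted p = 1.05e-05). The repair list had 8 members higher, 9 adjusted over the list alone, and 8 lower; its median (0.11) was above 0 and fry pointed down (adjusted p = 0.0200, but 0.0529 without day 3 replicate 2, 0.069 without day 7 replicate 3 and 0.0757 with the replicate number as a block). Growth factors had 9 members higher, Bdnf 4.80-fold, and 10 lower, with a median of -0.12 but an upward mean and fry direction (adjusted p = 0.00493). Immediate early genes rose in 13 of 14 cases (median 0.92). Of all genes 3850 were higher and 3699 lower at day 7. With libraries thinned to the smallest, 1248 and 1092 were called, and of 8139 own-class genes 2308 and 2142.

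**Figure D2:**
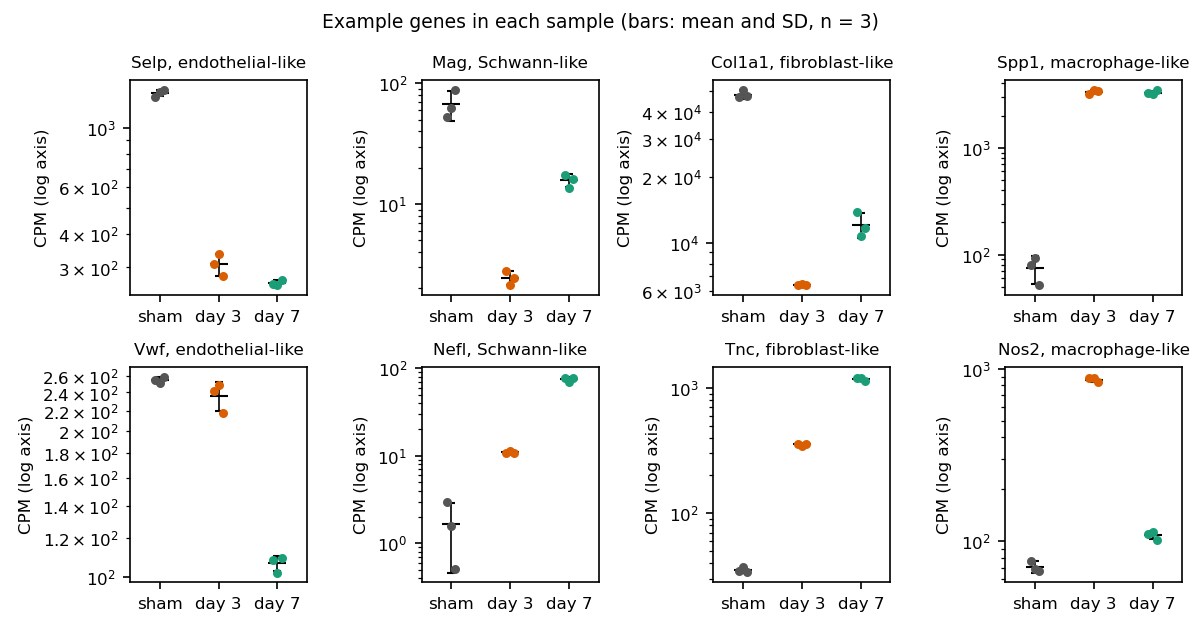
CPM (log axis) of 8 genes in the summed counts of their class, sham, day 3 and day 7; points are samples and bars the mean and SD of 3 samples. Mag fell from a mean of 67.8 to 2.46 CPM at day 3, Tnc rose from 35.04 to 1177 CPM at day 7, and Nos2 peaked at 866 CPM at day 3.

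Fibroblast-like cells at day 3 held less of the transcripts of Col1a1 and more of those of division than in sham. Col1a1, encoding the chief chain of type I collagen, fell from 48202 ± 2169 to 6386 ± 41.6 CPM (n = 3; log2 fold change -2.92 ± 0.08, adjusted p = 5.12e-16), and Sparc, a collagen-binding matrix protein gene, 5.84-fold. Il11, encoding a cytokine of the interleukin 6 family, rose from 3.12 ± 0.382 to 80.1 ± 2.83 CPM (4.68 ± 0.07, adjusted p = 5.34e-21), and Tnc, encoding the injury-induced matrix protein tenascin C, rose 10.1-fold. In all, 5882 of 15986 tested genes were higher and 6176 lower.

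Hmga2 (5.45), the kinase gene Nek10 (5.16), Spc24 (4.90) and Ube2c (4.61) were the other largest rises, and the largest falls were Ucma (509 ± 29.4 to 14.5 ± 2.97 CPM, -5.14), the matrix genes Fmod (-4.29) and Col9a1 (-3.92), and the enzyme genes Ces1d (-3.87) and Cpz (-3.64). Of the extracellular matrix list 11 of 19 members fell and 5 rose (median -0.26, fry adjusted p = 5.11e-07). Growth factor genes rose in 14 of 21 cases and fell in 7 (median 0.69, fry adjusted p = 3.45e-07); Nrg1, the neuregulin that signals to Schwann cells, rose 8.49-fold to 44.9 ± 3.49 CPM, although its CPM was higher in macrophage or monocyte-like cells, and Fgf10 fell 4.97-fold. Of the chemokine and cytokine list 9 of 14 members fell, Ccl11 2.98-fold, and 4 rose, Cxcl13 6.08-fold. That list had a median of -0.34, a mean of 0.01 and a downward fry direction (adjusted p = 0.00959), which became 0.053 without sham replicate 1 and 0.0577 to 0.136 without any 1 of the day 3 libraries, and 0.617 with the replicate number as a block. Cell cycle genes rose in 22 of 24 cases (median 3.44, fry adjusted p = 2.59e-07). Guidance genes other than netrin rose in 9 and fell in 11 of 21 cases (12 adjusted over the list alone; median -0.23, fry adjusted p = 3.54e-05), Sema3b falling 4.98-fold. Immediate early genes fell in 13 of 14 cases (median -1.40), and list-alone counts of the other lists were equal. The sham cells lay in clusters 3, 5, 6 and 7 and the day 3 cells in clusters 4 (44.1%), 10 (28.0%) and 22 (22.3%). Median depths were 8873 and 14367 UMIs. Ucma, Col1a1, Fmod and Cpz were among the top 10 genes of cluster 3, and Col9a1 of cluster 5. These clusters held 28.2% and 27.0% of fibroblast-like cells in sham, but 1.62% and 0.442% at day 3 and 1.75% and 0.0787% at day 7. Whether the falls of these genes came from this changed mix of clusters or from changes within cells was not tested. Of 5999 own-class genes, 2840 were higher and 2098 lower.

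At day 7 fibroblast-like cells held large amounts of tenascin transcripts against sham. Tnc rose from 35.04 ± 1.56 to 1177 ± 44.4 CPM (log2 fold change 5.07 ± 0.05, adjusted p = 1.71e-23), and Tnn, encoding tenascin W, from 0.495 ± 0.157 to 114 ± 9.63 CPM (7.84 ± 0.12). Msln, encoding the surface protein mesothelin, rose 109.9-fold and the adhesion molecule gene Ncam1, at a higher CPM in Schwann-like cells, 25.9-fold. Col1a1 stood at 12082 ± 1609 CPM (-2.00 ± 0.07). In all, 6291 genes were higher and 6192 lower.

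The largest falls at day 7 were Col9a1 (-5.64), Ces1d (-5.05), Ucma (-4.97), the cholecystokinin gene Cck (-4.197) and Smpd3 (-4.16). The matrix list had 7 of 19 members higher and 9 lower, a median of -0.10, a mean of 0.17 and an upward fry direction (adjusted p = 4.68e-05). Chemokine and cytokine genes fell in 11 of 14 cases, 12 adjusted over the list alone (median -0.49, fry adjusted p = 1.38e-06), and Cxcl13 rose 10.9-fold and the complement gene C3, highest in neutrophil-like cells, 7.66-fold. Growth factors rose in 10 and fell in 6 cases (median 0.20, fry adjusted p = 5.68e-04), Nrg1 rising 16.2-fold. Cell cycle genes rose in 21 of 24 cases (median 2.49, fry adjusted p = 2.84e-06), and immediate early genes in 10 of 14 (median 0.35, fry adjusted p = 7.52e-04). Guidance genes rose in 11 and fell in 7 cases (median 0.57), and the fry adjusted p of 0.0414 became 0.0529 to 0.424 when any 1 of the sham or day 3 libraries was left out and 0.104 with the replicate number as a block. The day 7 cells lay mainly in cluster 1 (59.8%), at a median of 9831 UMIs. In fibroblast-like cells the mural marker sum was 247 CPM in sham, 216 at day 3 and 618 at day 7, the macrophage marker sum 301, 682 and 684 CPM, and the median mitochondrial share of UMIs 2.21%, 2.26% and 4.01%. Of 6004 own-class genes, 3033 were higher and 2027 lower.

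Matrix genes of fibroblast-like cells rose between day 3 and day 7 while division genes and most cytokine genes of the list fell. C1qtnf3 rose from 6.57 ± 1.08 to 70.9 ± 0.862 CPM (log2 fold change 3.43 ± 0.07, adjusted p = 1.86e-15) and the heat shock gene Hspa1b 16.7-fold. Nek10 fell from 76.0 ± 0.449 to 3.88 ± 0.372 CPM (-4.29 ± 0.06), Il11 from 80.1 ± 2.83 to 9.34 ± 0.673 CPM (-3.10 ± 0.06) and Nppb, encoding a natriuretic peptide, from 74.8 ± 9.82 to 10.2 ± 0.458 CPM (-2.88 ± 0.13). Of the matrix list 13 of 19 members rose and 4 fell (median 0.74, fry adjusted p = 1.19e-07), Col1a1 by 1.89-fold and Sparc by 1.89-fold. All 24 tested cell cycle genes fell (median -0.73, fry adjusted p = 2.8e-05). Chemokine and cytokine genes fell in 8 of 14 cases and rose in 3, 4 adjusted over the list alone (fry adjusted p = 3.03e-06). Growth factors fell in 10 cases, Gdnf 2.10-fold, and rose in 8 (fry adjusted p = 1.85e-06). Guidance genes rose in 13 of 21 cases (fry adjusted p = 1.26e-05) and immediate early genes in 13 of 14 (median 1.67). In all, 5472 genes were higher and 5386 lower at day 7, and of 7030 own-class genes 2768 and 2522.

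Macrophage or monocyte-like cells at day 3 held more of the transcripts of lipid handling than in sham and less of those of resident macrophages. Spp1, encoding osteopontin, rose from 74.9 ± 21.5 to 3336 ± 156 CPM (n = 3; log2 fold change 5.48 ± 0.14, adjusted p = 9.79e-12), and Gpnmb, a glycoprotein gene of lipid-laden macrophages, 14.2-fold to 2406 ± 47.7 CPM. Nos2, encoding inducible nitric oxide synthase, rose 12.2-fold to 866 ± 29.1 CPM, and Arg1, encoding arginase 1, 27.4-fold. Cd163, the haemoglobin scavenger receptor gene of resident macrophages, fell from 348 ± 10.8 to 144 ± 10.6 CPM (-1.27 ± 0.06), and F13a1 5.16-fold. In all, 4478 of 12937 tested genes were higher and 4158 lower.

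Cd8a (0.692 ± 0.683 to 69.5 ± 3.83 CPM, 6.64), the apolipoprotein gene Apoc1 (6.19) and the tenascin R gene Tnr (5.05) were among the 5 largest rises with Spp1 and Arg1; Cd8a was higher in T or NK-like cells at day 3. The largest falls were the lectin gene Cd209f (59.0 ± 0.664 to 0.573 ± 0.661 CPM, -6.64), Col19a1 (-5.91), Hspa1b (-5.41), Negr1 (-5.36) and the ribonuclease gene Rnase2 (-4.85). Of the lipid and phagocytosis list 15 of 18 members rose, 16 adjusted over the list alone, and 2 fell (median 0.96, fry adjusted p = 2.6e-08). The inflammatory list split into 7 higher, among them the neutrophil-rich S100a8 (4.85) and S100a9, and 6 lower of 16 (median 0.01, fry adjusted p = 2.40e-04). Resident macrophage genes fell in 7 of 10 cases (median -0.94, fry adjusted p = 3.18e-07) and interferon response genes in 10 of 14 (median -0.84, fry adjusted p = 1.19e-07), Rsad2 10.0-fold and Ifit2 5.46-fold. Hypoxia and glycolysis genes rose in 11 of 20 cases (median 1.06, fry adjusted p = 8.03e-08), Eno1 6.58-fold. Cell cycle genes rose in 19 of 24 cases (median 1.80, fry adjusted p = 1.34e-05), and immediate early genes fell in 13 of 14 (median -1.09). Of sham cells 97.1% lay in cluster 15 and of day 3 cells 90.8% in cluster 2, at median depths of 2257 and 6710 UMIs. The fibroblast marker sum in these cells was 11977 CPM in sham, 2123 at day 3 and 3405 at day 7, and the dendritic cell marker sum 1894, 480 and 921 CPM. The T or NK marker sum was 68.7, 113 and 168 CPM, but Cd8a, which rose in these cells, is 1 of those markers. The rise of that sum therefore does not show T cell transcripts carried over. The median mitochondrial share was 5.44%, 3.56% and 4.99%. Of 4814 own-class genes, 2246 were higher and 1622 lower.

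By day 7 macrophage or monocyte-like cells held more transcripts of Apoc1 and Apoc4 and less of the inflammatory list than in sham. Apoc1 rose from 1.25 ± 0.984 to 309.6 ± 33.1 CPM (log2 fold change 7.93 ± 0.21, adjusted p = 2.3e-16), Apoc4 from 0.339 ± 0.332 to 164 ± 12.4 CPM and the elastase gene Mmp12 from 3.38 ± 2.85 to 215 ± 33.3 CPM. Cd163 was 4.82-fold lower than in sham and F13a1 11.97-fold. In all, 4434 genes were higher and 4394 lower.

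Cd8a (7.76) and the synaptogyrin gene Syngr1 (5.50) were the other large rises, and the largest falls were Col19a1 (-6.94), Cd209f (-6.87), Rnase2 (-5.71), Negr1 (-4.25) and Tnfsf18 (-4.06). Of the lipid list 16 of 18 members rose (median 1.73, fry adjusted p = 2.19e-08). Inflammatory genes fell in 12 of 16 cases (median -1.29, fry adjusted p = 1.75e-07), while Nos2 was 1.53-fold higher than in sham. Resident genes fell in 8 of 10 cases (median -1.69, fry adjusted p = 9.1e-08) and interferon genes in 12 of 14 (median -1.48, fry adjusted p = 5.85e-08), Ifit3 10.1-fold. Hypoxia genes rose in 12 and fell in 7 of 20 cases (fry adjusted p = 1.38e-06), and cell cycle genes rose in 20 of 24 (median 1.86, fry adjusted p = 1.05e-05). Immediate early genes had 7 members higher and 4 lower, a median of 0.14, a mean of -0.03 and a downward fry direction (adjusted p = 0.677). Counts adjusted over the list alone were equal. Of day 7 cells 78.7% lay in cluster 11, at a median of 5592 UMIs, and of 4922 own-class genes 2223 were higher and 1812 lower.

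Inflammatory genes fell in macrophage or monocyte-like cells from day 3 to day 7: all 16 tested members of the list were lower (median log2 fold change -1.44, fry adjusted p = 8.03e-08). Nos2 fell from 866 ± 29.1 to 109 ± 5.81 CPM (-2.996 ± 0.055, adjusted p = 1.65e-37), the matrix gene Thbs1 from 427 ± 22.1 to 38.5 ± 6.37 CPM (-3.47 ± 0.08) and the serpin gene Serpinb2 from 51.9 ± 2.57 to 3.28 ± 1.45 CPM (-3.97 ± 0.12). Apoc4 rose 19.1-fold, Mmp12 5.58-fold and Ptcd3 3.98-fold. Lipid genes rose in 10 of 18 cases, 11 adjusted over the list alone (median 0.33, fry adjusted p = 9.97e-05), while Spp1 differed by a log2 fold change of -0.02 ± 0.10 (adjusted p = 0.879). Interferon genes fell in 9 of 14 cases (fry adjusted p = 2.19e-06), hypoxia genes in 11 of 20 (fry adjusted p = 3.77e-07) and resident genes in 6 of 10, with 4 higher (fry adjusted p = 2.94e-05). Cell cycle genes had 8 members higher and 5 lower (fry adjusted p = 0.126), and immediate early genes rose in 13 of 14 (median 1.24). In all, 3504 genes were higher and 3468 lower at day 7, and 1773 and 1754 with libraries thinned to the smallest. Of 4211 own-class genes, 1323 were higher and 1358 lower.

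**Figure D3:**
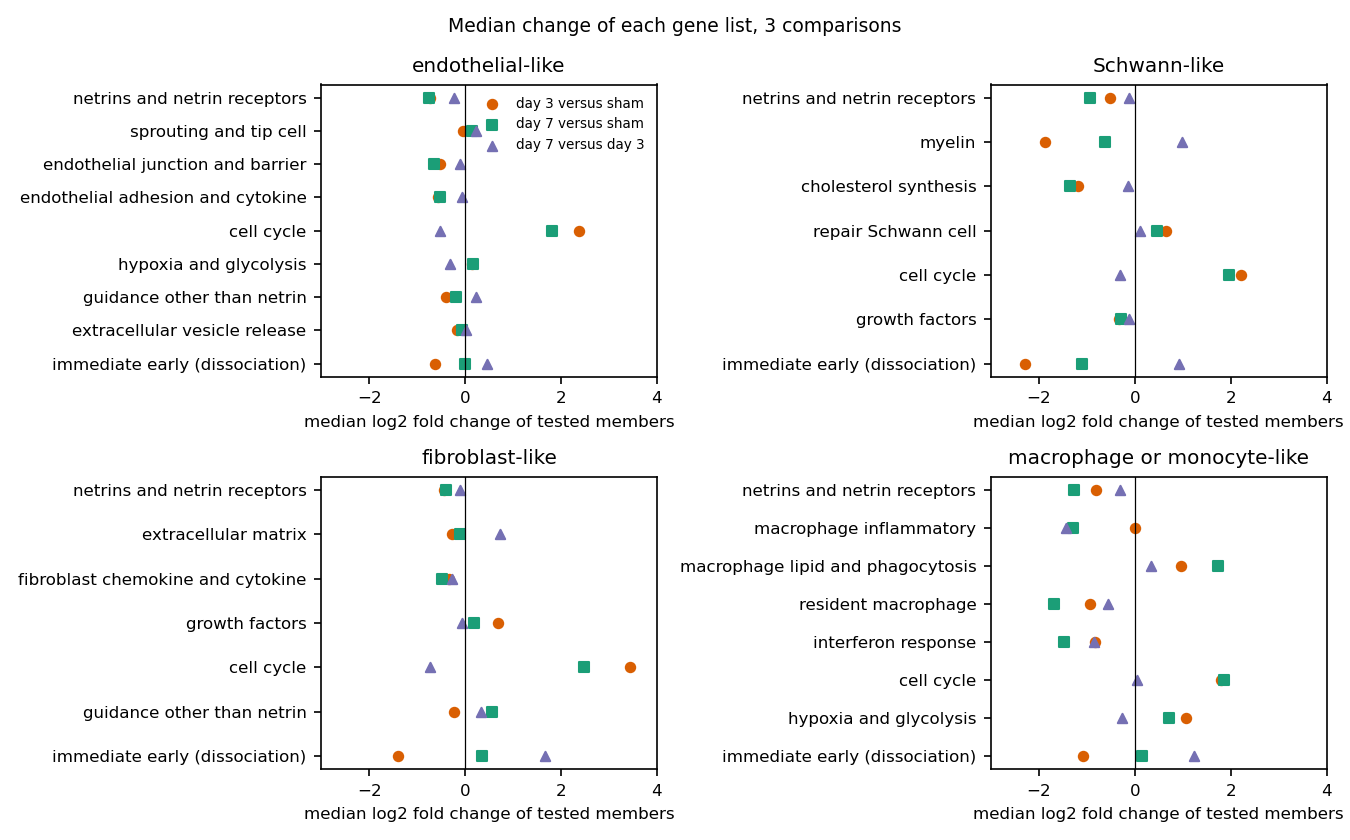
Median log2 fold change of the tested members of each gene list (x axis) in 4 cell classes for 3 comparisons (marker shape and colour). The cell cycle list lay between 1.80 and 3.44 at day 3 versus sham, and the myelin list moved from -1.88 at day 3 to -0.62 at day 7 versus sham.

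Ntn1 (ENSRNOG00000003947), the gene of the guidance protein in the series title, was lower after crush. In the summed counts of all cells it fell from 61.6 ± 2.37 CPM in sham to 15.9 ± 0.952 at day 3 (n = 3; log2 fold change -1.95 ± 0.05, adjusted p = 1.71e-16) and 14.1 ± 0.596 at day 7 (-2.13 ± 0.05, adjusted p = 7.97e-17). In endothelial-like cells it fell from 66.2 ± 3.88 to 16.3 ± 2.40 and 12.5 ± 0.997 CPM (-2.02 ± 0.10 and -2.39 ± 0.11 versus sham), and in fibroblast-like cells from 66.5 ± 2.87 to 21.5 ± 1.66 and 19.9 ± 1.09 CPM (-1.63 ± 0.05 and -1.74 ± 0.05). In Schwann-like cells the level was 18.2 ± 4.91, 12.6 ± 1.14 and 5.67 ± 0.658 CPM, and the day 3 call (-0.53, adjusted p = 0.0104) was lost without sham replicate 1 (0.0807) or sham replicate 3 (0.193). In macrophage or monocyte-like cells it fell from 28.9 ± 8.01 to 7.44 ± 0.630 and 6.11 ± 0.401 CPM. Within the clusters of fibroblast-like cells, whose mix also changed after crush, Ntn1 was not tested. By cluster, sham endothelial-like cells had 82.2 ± 4.42 CPM in cluster 25 and 42.1 ± 1.28 in cluster 18, and day 3 cells 42.1 ± 8.55 in cluster 18 and 15.5 ± 1.92 in cluster 17, where sham stood at 27.4 ± 20.7 CPM from 30 to 44 cells per sample and the log2 fold change against it was -0.54 ± 0.33 (adjusted p = 0.253). At day 7 the change within cluster 17 was -1.025 ± 0.353 against sham (adjusted p = 0.029) and -0.48 ± 0.18 against day 3 (adjusted p = 0.0409), and within cluster 18 -0.46 ± 0.29 (adjusted p = 0.19) and -0.42 ± 0.38 (adjusted p = 0.667). Between day 7 and day 3, the endothelial difference of -0.37 (adjusted p = 0.0416) was not called by DESeq2 (adjusted p = 0.114) or without any single library other than day 3 replicate 3 (0.0509 to 0.234).

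Shares of sham cells with an Ntn1 UMI differed among classes beyond their depth. Of sham endothelial-like cells 22.9% had a Ntn1 UMI (median 4617 UMIs per cell) and of fibroblast-like cells 31.9% (8873 UMIs), against 3.91% of T or NK-like cells (3223 UMIs), a class taken here as background. Thinned to 1500 UMIs per cell, with 480 endothelial-like and 74 T or NK-like sham cells too shallow and left out, the shares were 8.69% (95% exact interval 7.74 to 9.71) and 1.82% (0.845 to 3.46), and that of fibroblast-like cells was 8.06% (7.73 to 8.40), no longer above the endothelial one. Macrophage or monocyte-like cells had 6.16% of cells with a UMI in sham (2257 UMIs) and 4.01% thinned, and 1.20% and 0.985% thinned at day 3 and day 7. Schwann-like cells had 3.18%, 1.94% and 0.934% thinned in sham, day 3 and day 7. The sham macrophage share lay above the T or NK-like interval, although the intervals overlapped (3.22 to 4.90 against 0.845 to 3.46). The other shares of these classes lay within the T or NK-like interval of their group. The Ntn1 signal of Schwann-like cells, and of macrophage or monocyte-like cells after crush, was therefore not clear of background. At day 3 and day 7 the endothelial share was 11.9% and 7.66%, or 3.07% and 2.40% thinned, against 2.77% and 1.12% (0.992% and 0.852% thinned) in T or NK-like cells. Intervals cover counting error only.

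Among the genes of netrins and their receptors, several fell after crush, and Mcam, encoding the adhesion molecule CD146, rose in endothelial-like cells. Thinned to 1500 UMIs per cell, the share of endothelial-like cells with a Mcam UMI was 6.77% in sham, 13.3% at day 3 and 15.4% at day 7, against 1.01%, 1.58% and 2.45% in T or NK-like cells; fibroblast-like cells (0.632%, 1.79% and 2.07%) and macrophage or monocyte-like cells (0.962%, 1.67% and 1.91%) lay within the intervals of that background. In all cells together Neo1, encoding the receptor neogenin, fell 2.22-fold at day 3 and 1.60-fold at day 7, Unc5b 1.83-fold and 2.34-fold, Adora2b 2.05-fold and 1.62-fold, and Ntn4, another netrin gene, 1.77-fold and 3.18-fold. Unc5c fell 1.17-fold and 1.85-fold, and Mcam rose 2.34-fold and 2.91-fold to 56.1 ± 2.10 CPM. Ntn3 was at 0.605 ± 0.0873, 0.573 ± 0.125 and 1.58 ± 0.0982 CPM, rising at day 7 (adjusted p = 1.94e-07). Dcc (-1.28 and -1.62) and Dscam (-0.94 and -1.60) fell from under 1 CPM, a depth at which single cells carry almost no UMIs. Sums over all cells mix changes within cells with the changed shares of classes.

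Within classes, the netrin list had 5 of 7 tested members lower and 1 higher in endothelial-like cells at day 3 (median -0.73, fry adjusted p = 6.47e-05) and 5 lower and 2 higher at day 7 (median -0.76), when Unc5b, encoding a repulsive netrin receptor, stood at 34.1 ± 3.08 CPM against 27.0 ± 1.36 in sham (adjusted p = 0.00681). In Schwann-like cells 6 of 8 fell at day 3 (fry adjusted p = 3.86e-04) and 6 at day 7 (8.38e-05), Mcam among them, 1.41-fold and 1.28-fold. In fibroblast-like cells 6 of 9 fell and 2 rose at day 3, 3 adjusted over the list alone (fry adjusted p = 4.58e-05), and 7 fell and 2 rose at day 7 (3.27e-05). In macrophage or monocyte-like cells, where the thinned sham shares of Neo1 and Ntn4 (0.629% and 0.835%) were not above those of T or NK-like cells (1.15% and 1.10%), 6 of 8 fell at day 3 (6.24e-05) and 5 at day 7 (2.74e-05). The thinned sham shares of Neo1 and Ntn4 in endothelial-like cells (0.934% and 0.886%) were not above that background either. In Schwann-like cells the Ntn4 share, 1.16%, lay within the T or NK-like interval (0.333 to 2.37). Falls of these members in these classes cannot be told from a fall of background. From day 3 to day 7 the fry adjusted p of this list was 0.932 in endothelial-like, 0.001500 in Schwann-like, 0.169 in fibroblast-like and 0.00670 in macrophage or monocyte-like cells, the last becoming 0.0529 without day 7 replicate 2. Other list-alone counts were equal, apart from 2 in place of 3 falls in macrophages from day 3 to day 7.

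**Figure D4:**
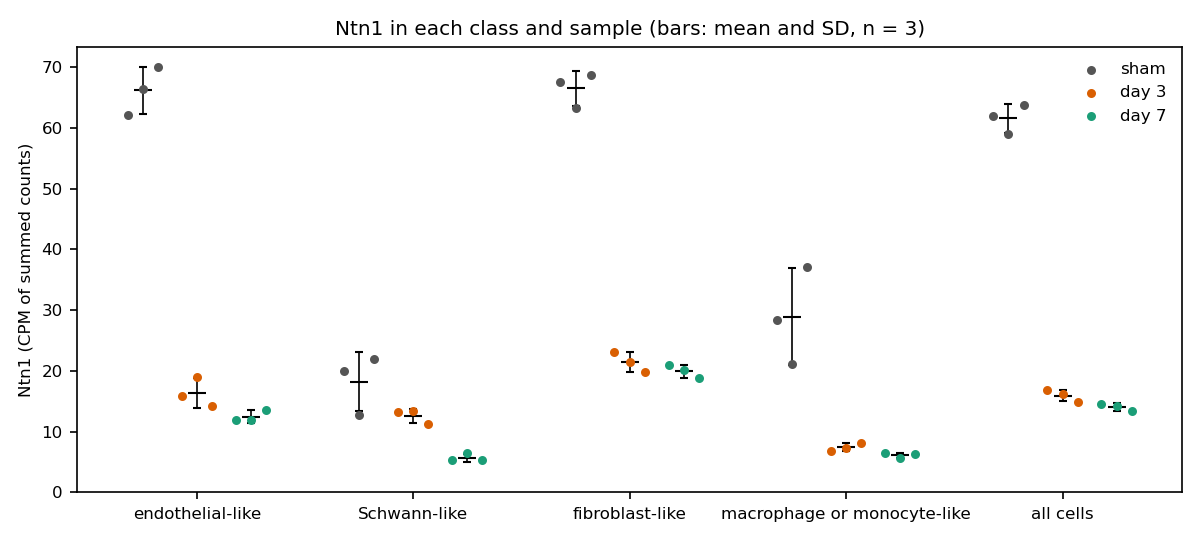
Ntn1 in CPM of the summed counts of 4 cell classes and of all kept cells, sham, day 3 and day 7; points are samples and bars the mean and SD of 3 samples. Every sham sample lay above every crush sample in endothelial-like cells, with group means of 66.2, 16.3 and 12.5 CPM.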

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

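The tests of this part were set down before their results were seen, apart from 2 reading rules given where they apply.

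The 3 libraries of a group lay close together. If they had been drawn from 1 pool of cells, the variance of log CPM between them was to be under 1.5 times that after shuffling cells among libraries; the median ratio over 4 classes and 3 groups was 2.12, with 12 ratios from 1.01 to 8.24 and 3.52 to 8.24 in fibroblast-like cells. A ratio of 2 or more was first set to exclude a pool, but separate captures of 1 suspension also add variance, a reading made after the ratio was seen, so pooling and separate animals cannot be told apart here. A small spread between animals was not tested.

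Fibroblast genes fell after crush in macrophage or monocyte-like cells. Doublets were argued against, since the median sham cell held 0.904 of the mean share of UMIs from 110 fibroblast genes, where a few doublets would leave it near 0. Free RNA from fibroblasts, which made up more of the sham nerve, is consistent with the values: over those genes the day 3 change in macrophages followed that in all cells (Pearson r = 0.924, across genes, which are not independent), with 100 lower and 6 higher. The 110 genes were chosen from the same sham samples, at 200 CPM or more in fibroblast-like cells. Their level there was at least 4 times that in endothelial-like, macrophage or monocyte-like, T or NK-like and B or plasma-like cells. The sums of all cells also include the macrophages. Both r and the counts therefore rest on a set drawn from the compared data. A fall of these genes within macrophages stays open.

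Ntn1 fell in endothelial-like cells. Free RNA was argued against as the source of the sham signal: at 1500 UMIs per cell the share of cells with a UMI was 4.77 times that of T or NK-like cells. Another mix of endothelial clusters after crush may account for the fall: within clusters 17 and 18 the day 3 log2 fold changes were -0.54 ± 0.33 and -0.03 ± 0.28 (SE). At day 7 they were -1.025 ± 0.353 (adjusted p = 0.029) and -0.46 ± 0.29 (0.19); the call in cluster 17 rests on a sham level of 27.4 ± 20.7 CPM (SD) against 10.6 ± 0.35. Taking both clusters was chosen after the values were seen, the sham cells of cluster 17 held 27 Ntn1 UMIs, and cluster 25, which held 48.6% of sham cells, had 22 and 40 cells after crush, so the tests leave the mix open. Whether cluster 25 was a lost type or a changed state was not tested.

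For several genes the change from sham had opposite signs at day 3 and day 7, and the difference between the days was tested with edgeR. The log2 fold changes of day 7 versus day 3 were -1.05 for Abcb1a in endothelial-like cells, and in Schwann-like cells 3.45 for Cldn19, 2.93 for Pmp2, -1.78 for Mapt and -2.00 for Sesn2. In fibroblast-like cells they were 2.36 for Fos, 4.06 for Hspa1b and -0.84 for Unc5c, in macrophage or monocyte-like cells -3.97 for Serpinb2 and in all cells -1.93 for Unc5a, a gene at 0.231 CPM or less. Calls against sham were lost under some alternatives, with the sign kept, for Abcb1a, whose day 7 fall lost its call when thinned (-0.18, adjusted p = 0.0577) and without day 7 replicate 1 (0.0851), and for Unc5a, whose rise at day 3 (0.0505) and fall at day 7 (0.0602) were not called by DESeq2, nor the fall without sham replicate 2 or day 7 replicate 1 or 3 (0.058 to 0.0786). Outside the compared classes, unnamed clusters 14 and 19 made up 3.87% and 4.26% of cells at day 7, against 0.903% and 0.0930% in sham.

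Other groupings of the samples were tested for the counts of called genes. Over the 3 groups, 1 of 100 splits, the real one, called as many genes in each class. It called 8711 against at most 6125 for other splits in endothelial-like, 10693 against 5795 in Schwann-like, 14334 against 7253 in fibroblast-like and 10528 against 6314 in macrophage or monocyte-like cells. These values argue against a chance assignment of libraries to groups. They cannot exclude a chance difference between animals or batches, because the test takes each library as independent, which the labels do not state. For pairs of groups, 10 splits are too few for a share under 0.05. The real totals for day 3 and day 7 versus sham and day 7 versus day 3 were 7583, 7694 and 3329 in endothelial-like, 8223, 8045 and 7549 in Schwann-like, 12058, 12483 and 10858 in fibroblast-like and 8636, 8828 and 6972 in macrophage or monocyte-like cells, and the highest of the other splits called 0 in every case.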

How the results depend on the processing

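All alternatives below were set before the data were examined except the count of own-class genes, added after the results were seen, and the DESeq2 test, set before but changed by turning off its independent filtering after the results were seen. Among gene counts 464 values stayed within 1.5 times and 28 moved. Own-class genes alone are fewer genes, and their numbers are given with each comparison above. In endothelial-like cells they gave 1889 higher and 1787 lower for day 3 versus sham, 1983 and 1849 for day 7 versus sham and 767 and 810 for day 7 versus day 3. In fibroblast-like cells they gave 2840 and 2098, 3033 and 2027, and 2768 and 2522, and in macrophage or monocyte-like cells 2246 and 1622, 2223 and 1812, and 1323 and 1358. In Schwann-like cells they gave 3349 higher and 2044 lower at day 3, 3419 and 1867 at day 7, and 2308 higher and 2142 lower for day 7 versus day 3. DESeq2 called 1098 genes lower for day 7 versus day 3 in endothelial-like cells (the cause was not tested). Thinning to the smallest library, which leaves fewer counts, gave 1248 higher and 1092 lower for day 7 versus day 3 in Schwann-like cells, 1773 and 1754 in macrophage or monocyte-like cells, and 6747 genes that differed among the groups in Schwann-like cells. The other size factors moved the median log2 fold change of all genes by -0.0361 to 0.0241.

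Of the share differences, 462 values kept direction and side of the threshold, 10 reversed and 23 were no longer past it. At Leiden resolution 2 the difference in percentage points was -0.0825 for B or plasma-like and 7.56 for mural-like cells at day 7 versus sham, and 0.2501 for perineurial-like cells at day 3. With classes from the marker share of each cell, lymphatic endothelial-like cells differed by 4.62 at day 3 and 0.279 at day 7, mural-like cells by 3.89 and neutrophil-like cells by -0.168 at day 7 versus sham, and mast-like and perineurial-like cells by 0.226 and 2.42 at day 7 versus day 3. With doublets kept, mast-like cells differed by 0.00943 between day 7 and day 3. The edgeR test of cell counts gave log2 ratios of -1.38 for mast-like (adjusted p = 0.263) and -1.67 for perineurial-like cells (0.0662) at day 7 versus day 3. With each library left out, the mast-like difference lay between -0.501 and -0.395 at day 3, -0.563 and -0.495 at day 7, and -0.123 and -0.0169 between the days, with an adjusted p of 0.0821 to 0.179 where the call was lost. The cause was not tested. Clustering without 15451 called genes left 90.4% to 91.6% of cells unnamed and gave no shares.

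Of list tests 996 kept their call, 23 lost and 4 gained it, and of named gene tests 9524 kept it, 135 lost and 45 gained it and 2 reversed. Those were Lss in Schwann-like cells at day 7 versus day 3 when thinned (log2 fold change -0.17, adjusted p = 0.699) and Cd209f in macrophage or monocyte-like cells at day 7 versus day 3 without day 3 replicate 3 (1.32, adjusted p = 0.046, with a range of -0.68 to 1.32 over single libraries left out). The cause was not tested.

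Expression gave no sign that replicate numbers paired the samples. Same-numbered samples had correlations of -0.299 to 0.233 over the classes and other samples -0.353 to 0.435. In 23 of 90 comparisons the own number was the best match. A pairing that left no trace in expression cannot be excluded. With the number as a block, endothelial-like cells at day 3 gave 3838 genes higher and 3740 lower, no count moved by over 1.5 times, and the share tests reached their smallest exact p, 0.02778. The block ended the call of 4 lists: chemokines at day 3 (adjusted p = 0.617) and guidance at day 7 (0.104) in fibroblast-like cells, guidance at day 7 in endothelial-like cells (0.0791) and repair genes at day 7 versus day 3 in Schwann-like cells (0.0757). Depth limited Schwann-like and macrophage or monocyte-like cells most, with sums down to 1565946 and 2531577 UMIs.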

Other observations

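The classes of the first paragraph were chosen after their values were seen, and their Ntn1 levels were not tested. In sham, Ntn1 was highest outside the 4 compared classes. Of 140 sham perineurial-like cells 60.0% had a Ntn1 UMI (95% exact interval 51.4 to 68.2, median 4895 UMIs), 27.1% after thinning to 1500 UMIs per cell, at 232 CPM in the summed counts. Of lymphatic endothelial-like cells 33.9% in sham, 31.2% at day 3 and 29.9% at day 7 had a UMI (864, 189 and 67 cells), or 16.5%, 14.9% and 14.8% thinned, against 1.82%, 0.992% and 0.852% thinned in T or NK-like cells (median 3223, 3249 and 2367 UMIs). Their summed CPM was 144, 96.5 and 115, in few cells. Lymphatic endothelial-like and perineurial-like cells made up 2.06% and 0.333% of cells in sham and 0.173% and 0.0168% at day 7, when 1 library held 49 of 67 lymphatic endothelial-like cells and the perineurial-like cells numbered 4, 0 and 3. With classes from the marker share of each cell, the lymphatic difference at day 7 was 0.279 percentage points, in the other direction.

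Among other netrin genes, fibroblast-like cells had Ntn3 at 0.738 ± 0.124 CPM in sham, 0.961 ± 0.185 at day 3 and 2.42 ± 0.125 at day 7 (day 7 versus sham log2 fold change 1.71 ± 0.15, edgeR adjusted p = 2.05e-09, n = 3). Unc5c in the same cells was at 7.69 ± 0.292, 10.4 ± 0.570 and 5.85 ± 0.461 CPM. Cd8a, a T cell marker, had its highest CPM of all classes in macrophage or monocyte-like cells at day 7, at 150.2 ± 10.7 CPM.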
